A study of Mus musculus with 15 samples.

How the data were processed

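RNA from the striatum of male F1 and F2 mice was sequenced, and the labels give each library a code of generation, group and animal number. Animal numbers 1, 3, 6 and 7 recur in both saline groups and 2 and 9 in both METH groups. The labels do not say whether this reflects descent, and the test of the difference treats the libraries as unrelated. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 2.1.3b and build mm10 were used. Their order, settings, strandedness and the way counts were derived are not given in the sources used here. The deposited tables, 1 per generation, hold counts, FPKM and TPM for 45777 features, per the file headers. The deposited counts are whole numbers whose totals differ between libraries and were used as raw counts. FPKM and TPM are the authors' values, per the file headers. The 45 value columns were matched to samples by name. Without strand, reads of overlapping or antisense genes cannot be told apart, and levels of near-identical paralogs and pseudogenes are uncertain. Positions are 1-based, from an annotation table of assembly GRCm38.p6 (the same build as mm10), which placed 45679 features by gene ID. The labels give the cell type as neuronal, while the tissue is striatum.

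Groups and replicate numbers came from sample titles. Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. Each generation was fitted on its own table. The difference between generations was the interaction over all 15 libraries; generation itself coincides with the table and was not tested. CPM used TMM-scaled library totals. A group with 0 reads was given a floor of 3 counts over the group. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. List means of log2 CPM (prior count 2) were compared by two-sided exact permutation. The smallest p this allows is 0.0286 in F1, 0.0286 in F2 and 4.08e-04 for the difference.

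Before the data were examined, 40 gene lists, the tests, most alternatives and the rule for named genes were fixed; lists for the difference were tested after seeing the data. Per generation and direction, the rule named up to 10 genes past the threshold and, where fewer passed, the 5 with the smallest p, skipping predicted genes, clones and pseudogenes. It added up to 4 passing members per list, 20 fixed genes, and the 5 smallest p per direction for the difference. Of 1125 list memberships, 1089 had a symbol in the tables. Alternatives were DESeq2 1.42.0 (size factors or Wald test), limma-voom with and without quality weights, no filter, a mean CPM of at least 1, other thresholds, and 1 fit of all 15 libraries. Limma-trend on deposited TPM and FPKM (log2 of TPM + 1, TPM + 0.1 and FPKM + 1), leaving out each library, and a replicate block were also tried. Added after seeing the data were a robust dispersion, a cortical marker mean as a covariate, and fits without libraries with Slc17a7 above 100 CPM or without F2 saline replicates 2 and 3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

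Of the 21 pairs of replicates, 0 agreed within sampling noise, as a library sequenced again would (chi-square per degree of freedom 16.1 to 65.8). Each library was counted as 1 replicate, as labelled. The steps were tested on simulated data with 200 changed genes. Simulated genes were drawn independently, with no structure shared between libraries, so detection and false calls in the real libraries may differ. For F1 (18126 genes), edgeR called 11.9% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 80.3% of those changed 4-fold, with 6 false calls. For F2 (17804 genes) the shares were 41.8%, 68.7% and 92.4%, with 11 false calls. For the difference (18993 genes) they were 20.9%, 53.7% and 74.2%, with 3 false calls.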

Results

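Striatal gene expression was measured by RNA sequencing in male ICR mice, an outbred stock, at 7 weeks of age. They came from 2 generations descended from males given methamphetamine (METH, a psychostimulant that releases dopamine) or saline. Per the labels, these founders were 6 weeks old, received 5 mg/kg METH or 10 mL/kg saline for 21 days, and were mated with untreated females. F1 mice were their sons, and F2 mice were sons of F1 males and untreated females. The 15 libraries comprised F1 saline (n = 4), F1 METH (n = 3), F2 saline (n = 4) and F2 METH (n = 4). Total counts per library ranged from 35044343 to 37659436 in F1 saline and from 32805918 to 38514778 in F1 METH. In F2 they ranged from 34622167 to 50573906 in saline and from 31563806 to 47199267 in METH mice. The labels do not tie animals to litters or founders, so the p-values compare group differences only with the spread between these animals. Animals that share a founder or litter would not be independent replicates of the founder's treatment, and the p-values could then be too small.

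The Y-linked gene Ddx3y was at 44.9 to 61.8 CPM in the 15 libraries, and Xist, the X-inactivation RNA, was at most at 1.45 CPM. Slc17a7, a vesicular glutamate transporter of cortical excitatory neurons, ran from 9.29 to 519 CPM in F1 saline and from 23.9 to 386 CPM in F1 METH. In F2 it ran from 9.94 to 183 CPM in saline and from 10.97 to 132 CPM in METH mice. It exceeded 100 CPM in F1 saline replicates 1 and 3, F1 METH replicate 3, F2 saline replicate 4 and F2 METH replicate 2.

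The first comparison asked whether the striatum of sons differed with the treatment of their sire. Prom1 (gene ID 19126, chromosome 5, 43993621 to 44102047), encoding the membrane glycoprotein prominin-1, was at 24.1 ± 1.90 CPM in saline and 37.6 ± 4.48 CPM in METH mice (mean ± SD, n = 4 and n = 3). Its log2 fold change was 0.64 (SE 0.11), and all 3 METH libraries lay above the saline libraries. Sorcs3 (gene ID 66673, chromosome 19, 48206025 to 48805505), a sorting receptor of neurons, was at 45.3 ± 6.71 CPM in saline and 27.9 ± 3.48 CPM in METH mice, a log2 fold change of -0.70 (SE 0.14). Nt5c1a (gene ID 230718, chromosome 4, 123201230 to 123225339), a cytosolic nucleotidase, was at 12.6 ± 2.09 CPM in saline and 6.39 ± 1.06 CPM in METH mice, a log2 fold change of -0.99 (SE 0.18). None of these passed edgeR's quasi-likelihood test, which called 0 of 18499 genes (smallest adjusted p = 0.785). At an unadjusted p under 0.05 there were 774 genes, 4.18% of those tested. DESeq2 called 7 genes and limma-voom 3.

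On the higher side, Bcas1 (gene ID 76960, chromosome 2, 170343973 to 170427911), a gene of myelinating oligodendrocytes, was at 196 ± 9.36 CPM in saline and 272 ± 39.8 CPM in METH mice, a log2 fold change of 0.47 (SE 0.10). Ephx1 (gene ID 13849, chromosome 1, 180989556 to 181017569), microsomal epoxide hydrolase, was at 21.0 ± 1.14 CPM in saline and 29.9 ± 3.97 CPM in METH mice. TrnL1 (gene ID 17735, chromosome MT, 2676 to 2750), a mitochondrial leucine tRNA gene, was at 27.6 ± 5.33 CPM in saline and 44.1 ± 2.48 CPM in METH mice. Whether its reads came from the tRNA or from longer mitochondrial transcripts was not tested. Mid1 (gene ID 17318, chromosome X, 169685199 to 169990798), an E3 ubiquitin ligase gene, was at 10.5 ± 5.66 CPM in saline and 64.8 ± 52.0 CPM in METH mice. Mid1 spans the pseudoautosomal boundary in laboratory mice, and repeated sequence there makes its level uncertain. On the lower side, Pxylp1 (gene ID 235534, chromosome 9, 96823336 to 96892688) had a log2 fold change of -0.55 (SE 0.11) and Klhl42 (gene ID 232539, chromosome 6, 147090615 to 147112778) one of -0.47 (SE 0.093). The edgeR adjusted p of these 6 genes was 0.994.

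Aox4 (gene ID 71872, chromosome 1, 58210397 to 58268600), an aldehyde oxidase gene beside close paralogs, had 94 reads over the F1 saline libraries and 0 over the F1 METH libraries. Against a floor of 3 counts over the group it was at least 22.4-fold lower (edgeR adjusted p = 0.785). The long noncoding RNA 1700041B01Rik had 0 reads in F1 saline and 72 in F1 METH, at least 33.5-fold higher by the same floor. Gm36170, another long noncoding RNA, had 0 and 38 reads, at least 17.7-fold higher. These bounds cover counting error only. Aox4, 1700041B01Rik and Gm36170 were the 3 genes called by limma-voom. DESeq2 called Aox4, 1700041B01Rik, Prom1, Nt5c1a, Sorcs3, Gm20517 and Gm34907. The genes named here with Gm or Rik symbols were chosen after their values were seen, and as predicted or noncoding genes their levels are uncertain.

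A set of 20 genes of dopamine, opioid and glutamate signalling, neuronal activity and related functions was described whatever its result. In F1, 19 were tested, 7 higher and 12 lower in METH mice. edgeR called 0 over all genes and 0 adjusted over the list alone (smallest adjusted p = 0.404), with 2 at an unadjusted p under 0.05. These were the activity-regulated gene Fos, at 30.3 ± 14.1 CPM in saline and 13.7 ± 6.64 CPM in METH mice, and the DNA methyltransferase gene Dnmt3a, at 172 ± 12.7 CPM in saline and 196 ± 4.81 CPM in METH mice. The dopamine receptor genes Drd1 and Drd2 had log2 fold changes of 0.057 (SE 0.17) and 0.23 (SE 0.21). Penk, encoding proenkephalin, was at 1557 ± 340.4 CPM in saline and 1685 ± 335 CPM in METH mice, and Pdyn, encoding prodynorphin, at 102 ± 24.0 CPM in saline and 76.8 ± 30.4 CPM in METH mice. For the set, further log2 fold changes were Th -0.028, Slc18a2 -0.34, Ppp1r1b 0.26, Adora2a 0.19, Egr1 -0.17, Arc -0.33 and Bdnf -1.07. Receptor and other genes stood at Oprm1 -0.37, Oprk1 -0.16, Gria1 -0.087, Grin2b -0.084 and Ttr 0.17, and Tac1 at 174 CPM in saline and 174 CPM in METH mice. Slc6a3, the dopamine transporter, was too low to be tested, at 0.107 CPM in saline and 0.0491 CPM in METH mice.

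Markers of glia and vessels were mostly higher in F1 METH mice, as log2 fold changes. Of 26 tested oligodendrocyte markers, 26 were higher, with a median of 0.25 (camera adjusted p = 2.28e-11, and adjusted p = 0.453 with an estimated correlation). Examples, here and for later lists, are among the 4 members of a list with the smallest p and were chosen after their values were seen: Mobp 0.43 (SE 0.16) and Apod 0.31 (SE 0.11). Of 20 tested endothelial markers, 17 were higher, with a median of 0.22 (camera adjusted p = 5.10e-08, and adjusted p = 0.185 with an estimated correlation). Members included Slco1a4 0.40 (SE 0.10) and Abcb1a 0.40 (SE 0.12), transporters of the blood-brain barrier. Of 20 tested astrocyte markers, 17 were higher, with a median of 0.17 (camera adjusted p = 2.37e-06, and adjusted p = 0.453 with an estimated correlation). Among them were Gjb6 0.43 (SE 0.16) and Slc1a2 0.40 (SE 0.16). Of 22 tested microglia and macrophage markers, 20 were higher, with a median of 0.19 (camera adjusted p = 3.20e-04, and adjusted p = 0.453 with an estimated correlation). Of 13 tested pericyte and smooth muscle markers, 12 were higher, with a median of 0.27 (camera adjusted p = 6.49e-05, and adjusted p = 0.185 with an estimated correlation). Examples were Vtn 0.30 (SE 0.090) and Rgs5 0.31 (SE 0.095). Of 18 tested fibroblast and meningeal markers, 16 were higher, with a median of 0.29 (camera adjusted p = 2.05e-04, and adjusted p = 0.185 with an estimated correlation). Col1a1 had 0.52 (SE 0.18). Adjusted over the list alone, 0 members of these lists passed, while Bcas1 passed within the oligodendrocyte precursor list.

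Of 13 tested mitochondrially encoded genes, 13 were higher, with a median of 0.27 (camera adjusted p = 1.22e-15, and adjusted p = 0.185 with an estimated correlation). The 13 genes took 8.25% ± 0.364 of all counts in F1 METH (SD, n = 3) and 7.02% ± 0.318 in F1 saline (SD, n = 4). The groups did not overlap in this share (two-sided exact permutation p = 0.0286, the smallest p this design allows). The list mean of the same 13 genes, the measure used for the other lists, did not reach that smallest p (exact permutation p = 0.0571). Of 38 tested interferon and innate immune genes, 33 were higher, with a median of 0.32 (camera adjusted p = 4.07e-08, and adjusted p = 0.361 with an estimated correlation). The interferon-induced GTPase genes gave Gbp3 1.06 (SE 0.24) and Gbp5 1.20 (SE 0.33). Of 22 tested circadian clock genes, 17 were higher, with a median of 0.18 (camera adjusted p = 2.37e-06, and adjusted p = 0.185 with an estimated correlation). The repressors gave Per3 0.41 (SE 0.12), Per2 0.68 (SE 0.22) and Ciart 0.77 (SE 0.26), and the activator Npas2 -0.27 (SE 0.090). Of 24 tested glucocorticoid responsive genes, 18 were higher, with a median of 0.19 (camera adjusted p = 3.55e-04, and adjusted p = 0.475 with an estimated correlation). Of 27 tested pan spiny projection neuron genes, 23 were higher, with a median of 0.096 (camera adjusted p = 0.0158, and adjusted p = 0.700 with an estimated correlation).

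On the lower side, of 39 tested heat shock and protein folding genes, 29 were lower, with a median of -0.14 (camera adjusted p = 6.40e-07, and adjusted p = 0.453 with an estimated correlation). Chaperone genes gave Ahsa1 -0.40 (SE 0.12) and Hspa8 -0.39 (SE 0.13). Of 36 tested members of the opioid system and neuropeptides list, 30 were lower, with a median of -0.32 (camera adjusted p = 3.05e-06, and adjusted p = 0.341 with an estimated correlation). The neuropeptide genes gave Tac2 -2.33 (SE 0.74) and Nts -1.35 (SE 0.50). Of 37 tested immediate early genes, 31 were lower, with a median of -0.19 (camera adjusted p = 0.00111, and adjusted p = 0.638 with an estimated correlation). Examples were Jun -0.31 (SE 0.12) and Btg2 -0.87 (SE 0.35). Of 76 tested nuclear oxidative phosphorylation genes, 58 were lower, with a median of -0.052 (camera adjusted p = 0.00785, and adjusted p = 0.700 with an estimated correlation). Of 21 tested members of the GABA synthesis, transport and receptors list, 16 were lower, with a median of -0.060 (camera adjusted p = 0.0134, and adjusted p = 0.475 with an estimated correlation). Gabra5 had -0.47 (SE 0.17). Of 46 tested imprinted genes, 33 were lower, with a median of -0.074 (camera adjusted p = 0.0175, and adjusted p = 0.549 with an estimated correlation). Of 5 tested erythrocyte genes, 5 were lower, with a median of -1.15 (camera adjusted p = 0.0216, and adjusted p = 0.638 with an estimated correlation). The erythrocyte list mean was 6.70 log2 CPM in F1 saline replicate 4 and at most 4.56 in the other F1 libraries. Cortical excitatory neuron markers, a list that was not called, were also mostly lower in F1 METH mice (16 of 21), and Slc17a7 was at 318 and 519 CPM in F1 saline replicates 1 and 3 and at 386 CPM in F1 METH replicate 3.

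With the preset correlation of 0.01, camera called 18 of 40 lists in F1, 11 higher and 7 lower. Of these calls 0 held with an estimated correlation (smallest adjusted p = 0.185), and fry called 0 (smallest adjusted p = 0.164). Two-sided exact permutation of list means has a smallest p of 0.0286 in F1, which most of the 40 lists would have to reach for any to pass after adjustment, so it is given unadjusted. At an unadjusted p under 0.05, 5 lists passed with an estimated correlation and 1 by permutation, the fibroblast and meningeal list at the smallest p.

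**Figure D1:**
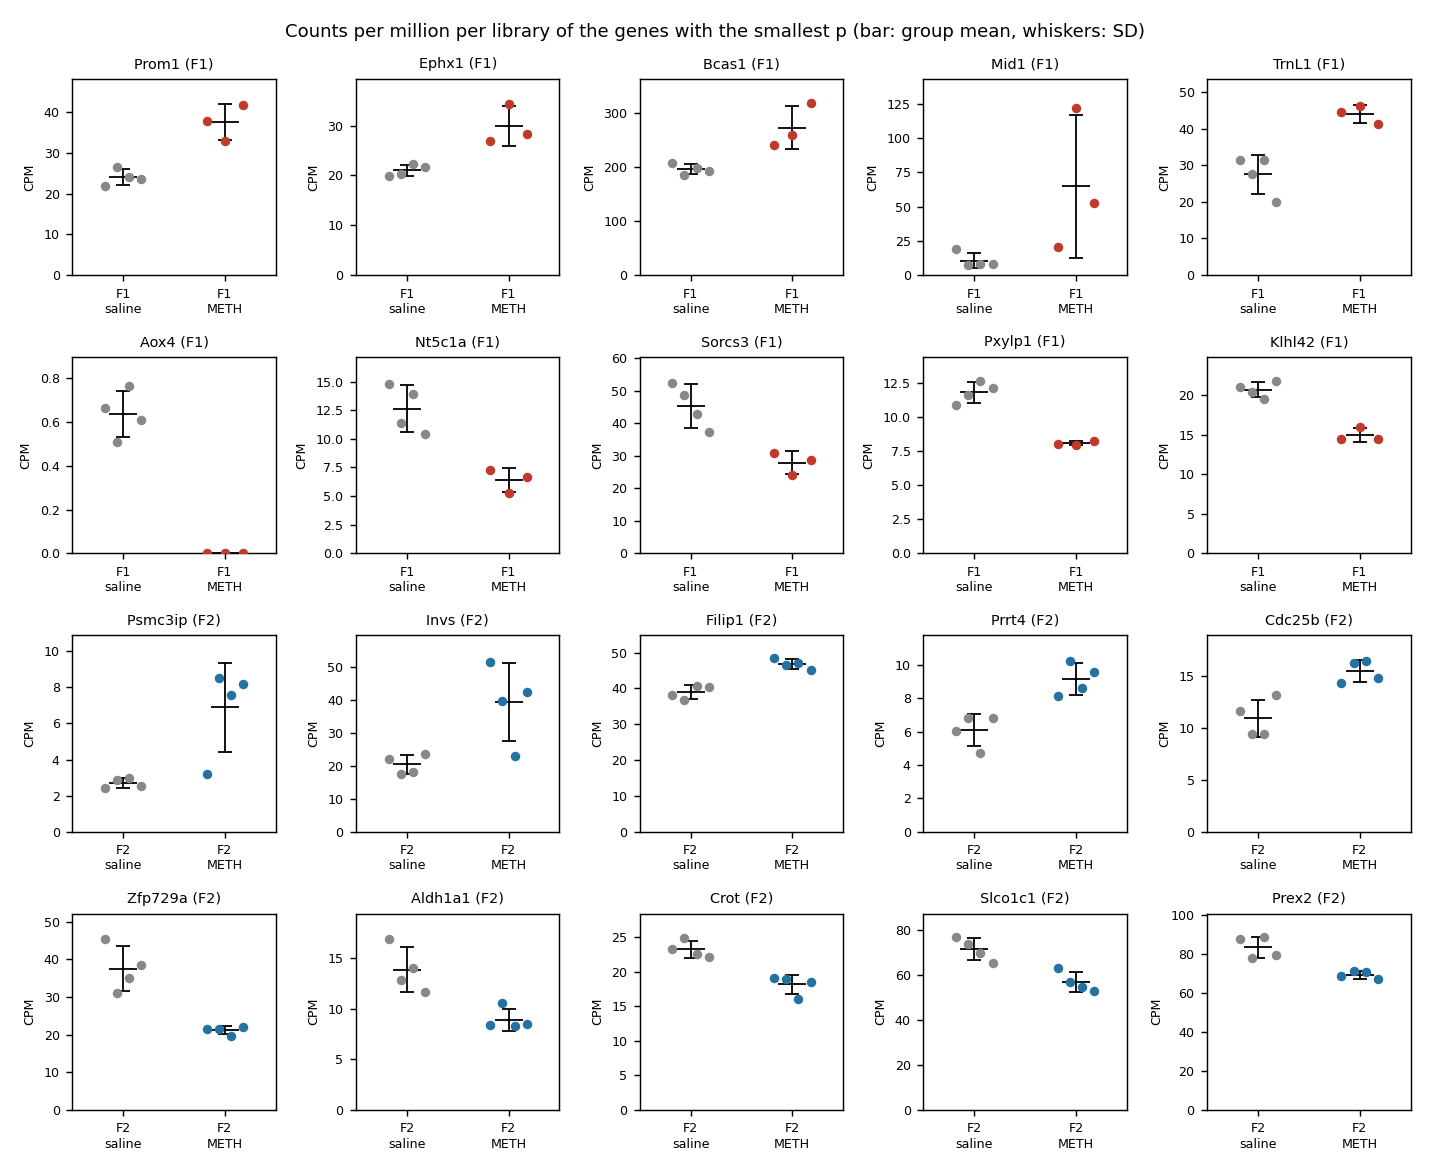
CPM (linear axes from 0) per library of the 10 genes per generation named for the smallest p, with F1 in the upper panels and F2 in the lower panels. Points are libraries of the saline (grey) and METH (coloured) groups, bars are group means and whiskers are SD; Aox4 is at 0 in the 3 F1 METH libraries.

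The second comparison asked the same question in grandsons. Zfp729a (gene ID 212281, chromosome 13, 67612760 to 67637803), a zinc finger gene with close paralogs that make its level uncertain, was at 37.6 ± 6.0 CPM in saline and 21.2 ± 1.06 CPM in METH mice (mean ± SD, n = 4 each). All 4 METH libraries lay below the saline libraries, with a log2 fold change of -0.83 (SE 0.11). Psmc3ip (gene ID 19183, chromosome 11, 101092141 to 101095435), a cofactor of meiotic recombination, was at 2.70 ± 0.277 CPM in saline and 6.89 ± 2.49 CPM in METH mice. Aldh1a1 (gene ID 11668, chromosome 19, 20492583 to 20643463), a retinaldehyde dehydrogenase found in dopaminergic neurons, was at 13.9 ± 2.24 CPM in saline and 8.92 ± 1.10 CPM in METH mice. edgeR called 0 of 18093 genes (smallest adjusted p = 0.182, Zfp729a), and 863 genes, 4.77%, had an unadjusted p under 0.05. DESeq2 called 9 genes and limma-voom 1. Without F2 METH replicate 1, in which it was lowest of its group, Psmc3ip passed edgeR's test (adjusted p = 0.0137).

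Invs (gene ID 16348, chromosome 4, 48279707 to 48431956), encoding the ciliary protein inversin, was at 20.4 ± 2.97 CPM in saline and 39.3 ± 11.9 CPM in METH mice, with 3 of 4 METH libraries above the saline libraries. Filip1 (gene ID 70598, chromosome 9, 79805018 to 80012851) had a log2 fold change of 0.26 (SE 0.062), Prrt4 (gene ID 101359, chromosome 6, 29169230 to 29179584) one of 0.59 (SE 0.14) and Cdc25b (gene ID 12531, chromosome 2, 131186436 to 131198511), a cell cycle phosphatase gene, one of 0.50 (SE 0.12). Slco1c1 (gene ID 58807, chromosome 6, 141524354 to 141570177), a thyroid hormone transporter of the blood-brain barrier, was at 71.3 ± 4.98 CPM in saline and 56.8 ± 4.41 CPM in METH mice. Crot (gene ID 74114, chromosome 5, 8966033 to 8997146), a peroxisomal carnitine acyltransferase, had a log2 fold change of -0.36 (SE 0.080) and Prex2 (gene ID 109294, chromosome 1, 10993273 to 11303683) one of -0.27 (SE 0.062). The long noncoding RNA Gm38515, called by limma-voom, had 0 reads in F2 saline and 58 in F2 METH, at least 20.01-fold higher against a floor of 3 counts over the group. DESeq2 called Gm38515, Zfp729a, Psmc3ip, Invs, Aldh1a1, B230110G15Rik, Gm46877, Gm8518 and 1700034P13Rik, the last pair among genes too low for edgeR's filter. The predicted and noncoding genes among them were chosen after their values were seen, and their levels are uncertain.

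Of the 20 genes described whatever their result, 19 were tested in F2, 12 higher and 7 lower in METH mice. edgeR called 0 over all genes and 0 adjusted over the list alone (smallest adjusted p = 0.451), with 1 at an unadjusted p under 0.05. This was Slc18a2, the vesicular monoamine transporter, at 0.895 ± 0.204 CPM in saline and 0.591 ± 0.0717 CPM in METH mice. Drd1 and Drd2 had log2 fold changes of 0.11 (SE 0.098) and 0.075 (SE 0.079). Penk was at 1391 ± 115 CPM in saline and 1408 ± 76.1 CPM in METH mice, and Fos at 30.9 ± 12.3 CPM in saline and 36.3 ± 3.45 CPM in METH mice. Further log2 fold changes were Th -0.034, Pdyn -0.077, Tac1 -0.096, Ppp1r1b 0.041, Adora2a 0.15, Egr1 0.037, Arc -0.059 and Bdnf 0.041. Those of the remaining genes were Oprm1 -0.22, Oprk1 0.12, Gria1 0.026, Grin2b 0.10, Dnmt3a 0.069 and Ttr -0.60. Slc6a3 was too low to be tested, at 0.120 CPM in saline and 0.159 CPM in METH mice.

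Chaperone and ribosomal protein genes were mostly lower in F2 METH mice, as log2 fold changes. Of 39 tested heat shock and protein folding genes, 39 were lower, with a median of -0.30 (camera adjusted p = 1.63e-22, and adjusted p = 0.475 with an estimated correlation). Chaperone genes gave Hspb1 -1.03 (SE 0.28) and Hspa1b -1.36 (SE 0.41). The list mean was 6.41 and 6.20 log2 CPM in F2 saline replicates 2 and 3, and 5.62 to 6.01 in the other F2 libraries. Without these replicates the median was -0.11. Of 79 tested cytosolic ribosomal protein genes, 73 were lower, with a median of -0.16 (camera adjusted p = 1.63e-22, and adjusted p = 0.475 with an estimated correlation). Examples were Rps23 -0.23 (SE 0.056) and Rps14 -0.38 (SE 0.11). Of 76 tested nuclear oxidative phosphorylation genes, 72 were lower, with a median of -0.11 (camera adjusted p = 3.01e-12, and adjusted p = 0.475 with an estimated correlation). Of 34 tested oxidative stress and metallothionein genes, 28 were lower, with a median of -0.085 (camera adjusted p = 0.00205, and adjusted p = 0.475 with an estimated correlation). Of 37 tested members of the opioid system and neuropeptides list, 27 were lower, with a median of -0.096 (camera adjusted p = 0.0290, and adjusted p = 0.475 with an estimated correlation). Crh, encoding corticotropin-releasing hormone, had -0.77 (SE 0.24). Of 24 tested glucocorticoid responsive genes, 16 were lower, with a median of -0.050 (camera adjusted p = 0.0290, and adjusted p = 0.785 with an estimated correlation). Of 48 tested imprinted genes, 32 were lower, with a median of -0.050 (camera adjusted p = 0.0103, and adjusted p = 0.475 with an estimated correlation).

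Markers of astrocytes, microglia, oligodendrocytes, endothelium and fibroblasts were mostly lower in F2 METH mice. In contrast, 10 of 13 pericyte and smooth muscle markers were higher, a list that was not called. Means of the lists named as lower spread more between F2 saline than between F2 METH libraries. The SD was 0.332 and 0.0928 log2 CPM for oligodendrocyte markers, and 0.169 and 0.0606 for astrocyte markers. Exact permutation of these list means gave p = 0.0571 (endothelial) to 0.657 (oligodendrocyte). Counts of lower members therefore do not establish a shift of the METH group. Of 20 tested astrocyte markers, 19 were lower, with a median of -0.17 (camera adjusted p = 1.82e-09, and adjusted p = 0.475 with an estimated correlation). Examples were Aldoc -0.23 (SE 0.068) and Slc1a3 -0.18 (SE 0.068). Of 22 tested microglia and macrophage markers, 20 were lower, with a median of -0.18 (camera adjusted p = 4.89e-06, and adjusted p = 0.475 with an estimated correlation). The complement genes gave C1qc -0.58 (SE 0.19) and C1qb -0.37 (SE 0.14). Of 13 tested oligodendrocyte precursor markers, 12 were lower, with a median of -0.20 (camera adjusted p = 0.00121, and adjusted p = 0.475 with an estimated correlation). Of 20 tested endothelial markers, 16 were lower, with a median of -0.12 (camera adjusted p = 0.00544, and adjusted p = 0.475 with an estimated correlation). Ly6c1 had -0.38 (SE 0.13). Of 26 tested oligodendrocyte markers, 24 were lower, with a median of -0.14 (camera adjusted p = 0.00744, and adjusted p = 0.847 with an estimated correlation). Of 18 tested fibroblast and meningeal markers, 12 were lower, with a median of -0.15 (camera adjusted p = 0.0386, and adjusted p = 0.819 with an estimated correlation). Of 13 tested choroid plexus markers, 10 were lower, with a median of -0.10 (camera adjusted p = 0.0444, and adjusted p = 0.475 with an estimated correlation). Of 12 tested thalamic and hypothalamic neuron markers, 11 were lower, with a median of -0.17 (camera adjusted p = 0.00333, and adjusted p = 0.462 with an estimated correlation). Of 27 tested pan spiny projection neuron genes, 23 were higher, with a median of 0.036 (camera adjusted p = 0.0444, and adjusted p = 0.847 with an estimated correlation). Adjusted over the list alone, Aldh1a1 passed within the dopamine list and 0 members of the lists above did.

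With the preset correlation of 0.01, camera called 16 of 40 lists in F2, 1 higher and 15 lower. Of these calls 0 held with an estimated correlation (smallest adjusted p = 0.462), and fry called 0 (smallest adjusted p = 0.339). Two-sided exact permutation of list means has a smallest p of 0.0286 in F2, which most of the 40 lists would have to reach for any to pass after adjustment, so it is given unadjusted. At an unadjusted p under 0.05, 3 lists passed with an estimated correlation and 2 by permutation, both lower in METH mice and at the smallest p. Those passing by permutation were thalamic and hypothalamic neuron markers, and serotonin, acetylcholine, adenosine and cannabinoid receptors. Without F2 METH replicate 1, camera called 10. Without F2 saline replicates 2 and 3, a choice made after seeing the data, camera called 19 lists at the preset correlation. That fit compared the 4 METH libraries with saline replicates 1 and 4 alone. Newly called higher were immediate early genes (adjusted p = 4.25e-15), cAMP and DARPP-32 signalling (adjusted p = 0.00327), circadian clock genes (adjusted p = 0.0215), D1 pathway spiny neuron markers (adjusted p = 0.0498) and D2 pathway spiny neuron markers (adjusted p = 0.0498), and newly called lower interferon and innate immune genes (adjusted p = 0.0155) and nuclear retained long noncoding RNAs (adjusted p = 0.0498). No longer called were glucocorticoid responsive genes (adjusted p = 0.602), whose camera direction turned from lower to higher, oxidative stress and metallothionein genes (adjusted p = 0.0680), opioid system and neuropeptides (adjusted p = 0.0586) and choroid plexus markers (adjusted p = 0.0546). With an estimated correlation, 0 lists were called in this fit (smallest adjusted p = 0.468), and that of immediate early genes was 0.500. The mitochondrial share of counts was 6.76% ± 0.631 in F2 METH and 6.55% ± 0.471 in F2 saline (SD, n = 4 each, two-sided exact permutation p = 0.6).

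Other lists passed camera's test in neither generation, and their median log2 fold changes in F1 and F2 are given in that order. Not called were D1 pathway spiny neuron markers (0.0058 and 0.069, adjusted p = 0.892 and 0.367) and D2 pathway spiny neuron markers (0.17 and 0.053, adjusted p = 0.0772 and 0.418). These medians were not called for striatal interneuron markers (-0.077 and -0.081, adjusted p = 0.135 and 0.0753) and cortical excitatory neuron markers (-0.28 and 0.0022, adjusted p = 0.195 and 0.962). Likewise not called were pallidal and septal neuron markers (0.10 and -0.0014, adjusted p = 0.135 and 0.903) and immature neuron and neuroblast markers (-0.11 and 0.079, adjusted p = 0.0772 and 0.367). No call was made for ependymal and ciliated cell markers (0.074 and 0.10, adjusted p = 0.0772 and 0.502) and dopamine synthesis, transport and receptors (0.038 and -0.032, adjusted p = 0.367 and 0.139). The test was not passed by cAMP and DARPP-32 signalling (-0.023 and -7.35e-04, adjusted p = 0.315 and 0.625) and glutamate receptors (0.0014 and 0.010, adjusted p = 0.965 and 0.776). Also not called were serotonin, acetylcholine, adenosine and cannabinoid receptors (-0.12 and -0.096, adjusted p = 0.293 and 0.219) and nuclear retained long noncoding RNAs (0.045 and -0.071, adjusted p = 0.195 and 0.502). Short of the threshold were DNA methylation and chromatin modifiers (0.014 and 0.022, adjusted p = 0.596 and 0.387) and neurotrophin and MAP kinase pathway genes (-0.019 and -0.020, adjusted p = 0.410 and 0.371). Not past it were extracellular matrix and axon guidance genes (-0.051 and -0.047, adjusted p = 0.315 and 0.139) and genes with known strain-variable expression in mouse brain (-0.044 and 0.0083, adjusted p = 0.239 and 0.989). Without a call were Y-linked and X-inactivation genes (0.10 and -0.022, adjusted p = 0.0853 and 0.619). The median, mean fold change and camera's direction differed in sign for D1 pathway spiny neuron markers, choroid plexus markers and glutamate receptors in F1 and for cortical excitatory neuron markers, ependymal and ciliated cell markers, cAMP and DARPP-32 signalling, glutamate receptors, circadian clock genes and genes with known strain-variable expression in mouse brain in F2. In called lists they had 1 sign.

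Lists called in F1 had these medians in F2, where they were not called. In F2 the medians were those of pericyte and smooth muscle markers (0.053, adjusted p = 0.435), erythrocyte genes (-0.089, adjusted p = 0.418) and GABA synthesis, transport and receptors (-0.032, adjusted p = 0.483). Uncalled in F2 were immediate early genes (0.041, adjusted p = 0.367), circadian clock genes (0.016, adjusted p = 0.881) and mitochondrially encoded genes (0.047, adjusted p = 0.371). F2 medians were given by interferon and innate immune genes (-0.048, adjusted p = 0.371). Of lists called in F2, those not called in F1 had the following F1 medians. In F1 the medians were those of thalamic and hypothalamic neuron markers (-0.11, adjusted p = 0.315), oligodendrocyte precursor markers (0.044, adjusted p = 0.135) and choroid plexus markers (-0.017, adjusted p = 0.622). Uncalled in F1 were oxidative stress and metallothionein genes (0.036, adjusted p = 0.238) and cytosolic ribosomal protein genes (-0.032, adjusted p = 0.238). Of 11 lists called in both generations, 5 had the same direction and 6 opposite directions.

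**Figure D2:**
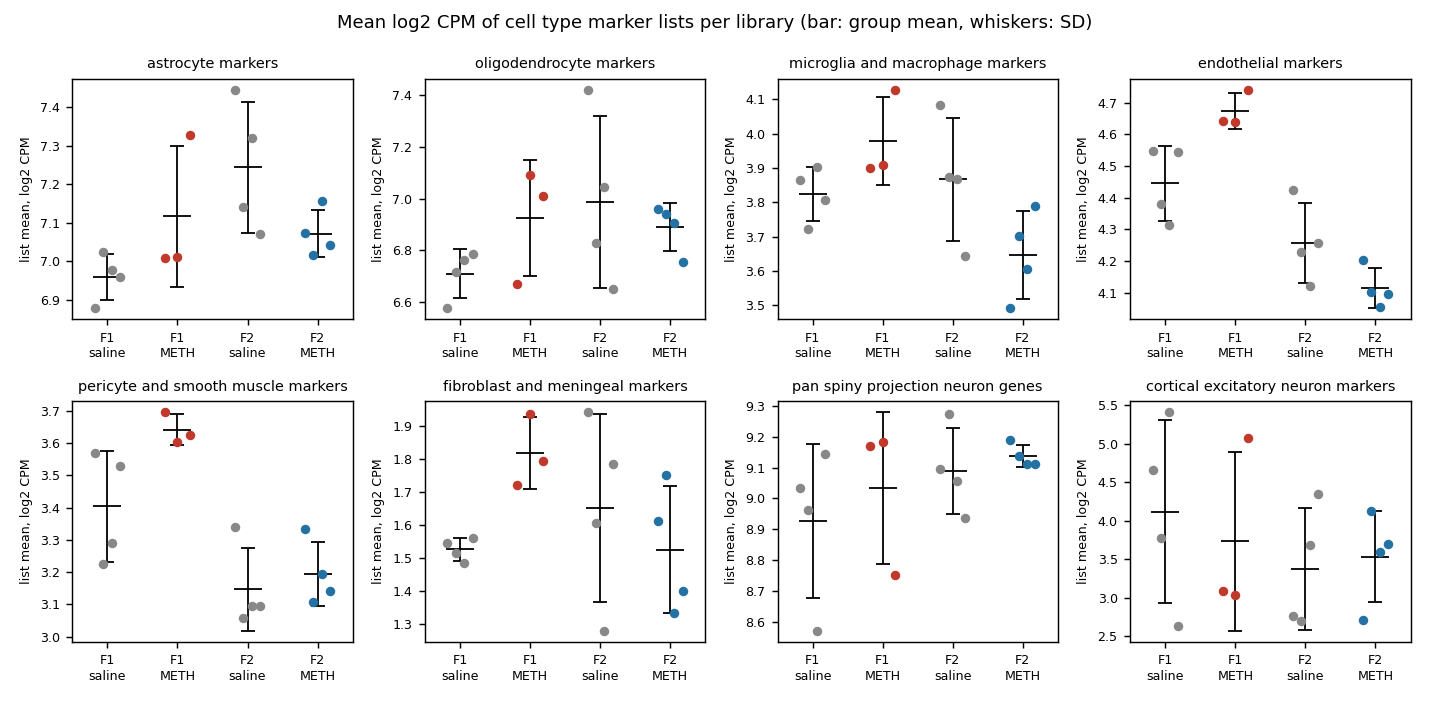
Mean log2 CPM over the tested members of 8 marker lists (vertical axes, each with its own range) per library in the F1 and F2 saline (grey) and METH (coloured) groups, with bars for group means and whiskers for SD. The 3 F1 METH libraries lie above the 4 F1 saline libraries for endothelial, pericyte and fibroblast markers.

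The third comparison asked whether the effect of the founder's treatment differed between the generations. Aox4 had 0 reads in F1 METH mice, whereas in F2 it was at 0.431 ± 0.174 CPM in saline and 0.450 ± 0.104 CPM in METH mice (mean ± SD, n = 4 each). It was the single gene of 19308 called by edgeR (adjusted p = 0.0317), with 943 genes at an unadjusted p under 0.05. DESeq2 called 4 genes, Aox4, Prex2, Tmem204 and Gm20517, the last a predicted gene chosen after its value was seen, and limma-voom called 0. The call of Aox4 was lost in 14 of 15 fits that left out a library (adjusted p = 0.0527 to 0.156) and held without F1 saline replicate 2 (adjusted p = 0.0335). The fitted difference of Aox4, which depends on the prior count as 1 group is at 0, was 7.61, and 7.44 to 7.77 in these 15 fits. After Aox4, the differences above 0 with the smallest p, given as log2 fold changes in F1 and F2, were those of Nt5c1a (-0.99 and -0.078), Sorcs3 (-0.70 and 0.091), Amer3 (-0.32 and 0.15) and Tspyl3 (-0.30 and 0.12). Below 0 they were those of Prex2 (0.36 and -0.27), Tmem204 (0.50 and -0.25), Prom1 (0.64 and -0.032), Il33 (0.34 and -0.33) and Phgdh (0.39 and -0.38). Il33 encodes an alarmin cytokine, and Phgdh the first enzyme of serine synthesis. Their edgeR adjusted p was 0.854 each. Positions not yet given were Amer3 (gene ID 211383, chromosome 1, 34578907 to 34590944), Tspyl3 (gene ID 241732, chromosome 2, 153222370 to 153225441), Tmem204 (gene ID 407831, chromosome 17, 25057702 to 25081114), Il33 (gene ID 77125, chromosome 19, 29925113 to 29960718) and Phgdh (gene ID 236539, chromosome 3, 98313171 to 98339969).

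For the lists, a difference below 0 means a smaller fold change in F2 than in F1. Of 20 tested astrocyte markers, 19 were below 0, with a median of -0.34 (camera adjusted p = 8.37e-14, and adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone, 7 of them passed, Aldh1l1, Aldoc, Apoe, Atp1b2, Cldn10, Gjb6 and Slc1a2. Adjusted over all genes, 0 members of any list passed. Adjustment within a list makes no allowance for the 40 lists, so passing it is weak support. Of 20 tested endothelial markers, 18 were below 0, with a median of -0.32 (camera adjusted p = 1.79e-09, and adjusted p = 0.126 with an estimated correlation). Of these, 3 passed adjusted over the list alone, Ly6c1, Mfsd2a and Slc2a1. Of 22 tested microglia and macrophage markers, 22 were below 0, with a median of -0.35 (camera adjusted p = 9.02e-09, and adjusted p = 0.33 with an estimated correlation). Of 26 tested oligodendrocyte markers, 25 were below 0, with a median of -0.39 (camera adjusted p = 1.29e-09, and adjusted p = 0.382 with an estimated correlation). In other lists Bcas1, Aldh1a1 and the RNA sensor gene Ifih1 passed adjusted over the list alone. Further called lists, with their medians and their adjusted p with an estimated correlation, follow. Called were mitochondrially encoded genes (-0.23, adjusted p = 0.372 with an estimated correlation) and interferon and innate immune genes (-0.32, adjusted p = 0.372 with an estimated correlation). The calls took in cytosolic ribosomal protein genes (-0.14, adjusted p = 0.667 with an estimated correlation) and glucocorticoid responsive genes (-0.30, adjusted p = 0.372 with an estimated correlation). Camera also called heat shock and protein folding genes (-0.18, adjusted p = 0.667 with an estimated correlation) and fibroblast and meningeal markers (-0.35, adjusted p = 0.372 with an estimated correlation). Another call covered circadian clock genes (-0.23, adjusted p = 0.372 with an estimated correlation) and oligodendrocyte precursor markers (-0.24, adjusted p = 0.382 with an estimated correlation). Calls extended to oxidative stress and metallothionein genes (-0.16, adjusted p = 0.382 with an estimated correlation) and immediate early genes (0.18, adjusted p = 0.667 with an estimated correlation). Calls were made for opioid system and neuropeptides (0.29, adjusted p = 0.389 with an estimated correlation) and nuclear oxidative phosphorylation genes (-0.069, adjusted p = 0.808 with an estimated correlation). Also called were pericyte and smooth muscle markers (-0.18, adjusted p = 0.382 with an estimated correlation) and immature neuron and neuroblast markers (0.19, adjusted p = 0.639 with an estimated correlation). Last came ependymal and ciliated cell markers (-0.098, adjusted p = 0.749 with an estimated correlation).

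With the preset correlation of 0.01, camera called 19 of 40 lists for the difference, 3 above and 16 below 0. Of these calls 0 held with an estimated correlation (smallest adjusted p = 0.126), and fry called 0 (smallest adjusted p = 0.109). Two-sided exact permutation of list means gave 0 after adjustment over the lists (smallest adjusted p = 0.0816). Fold changes in F1 and F2 had a Pearson r of 0.0283 and a Spearman rho of 0.0164 across 17838 genes, which are not independent replicates. For differences of mean log2 CPM, r was 0.00563, and 1166 of 1225 splits of the libraries gave an r as large in size (two-sided permutation p = 0.952). With 0 genes called by edgeR in either generation (774 and 863 at an unadjusted p under 0.05), 0 were shared, and 0 were shared by DESeq2 calls (7 and 9 genes). So few calls leave almost no overlap to find, so these counts say little about sharing.

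At an unadjusted p under 0.05, 23 genes were higher in F1 METH and lower in F2 METH mice, where 12.1 would fall by chance (two-sided Fisher's exact p = 0.00438, which treats genes as independent). They included the astrocyte genes Gjb6, Slc7a10 and Ndrg2, the endothelial genes Ly6c1 and Mfsd2a, and Il33, Phgdh and Prex2. Lower in both were 12 genes against 8.12 by chance (Fisher's exact p = 0.152), among them the chaperone genes Hspa1b, Stip1 and Fkbp4. Higher in both were 7 against 9.59 (Fisher's exact p = 0.507), and lower in F1 but higher in F2 4 against 6.41 (Fisher's exact p = 0.423). Members of these sets outside the fixed rule were chosen after their values were seen.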

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

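The tests of the neuronal share, of the mean of 6 lists and of lists between generations were chosen after the results were seen. In 7 of 240 checks, 1 library stood apart from the other 3 of its group by Dixon's ratio of gap to range, where chance gives about 12. For list means the ratio was 0.877 for D1 pathway markers (F2 METH replicate 3 lowest), 0.865 for pericyte markers (F2 saline replicate 1 highest) and 0.836 for glutamate receptors (F2 METH replicate 1 lowest). For genes it was 0.878 for Mid1 (F1 saline replicate 1 highest), 0.872 for Psmc3ip (F2 METH replicate 1 lowest), 0.900 for Aldh1a1 (F2 METH replicate 2 highest) and 0.830 for Crot (F2 METH replicate 3 lowest).

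The effect differed between generations for Aox4 (edgeR adjusted p = 0.0317), a call that did not hold with limma-voom (adjusted p = 0.412), with the replicate block (adjusted p = 0.532) or in 14 of 15 fits without a library (adjusted p = 0.0527 to 0.156). The fitted difference was 5.50, 7.68 and 7.44 to 7.77 in these fits, against 7.61 with all libraries. Of the splits of the libraries, 18 of 100 called at least 1 gene. List means differed before adjustment for astrocyte markers (two-sided exact permutation p = 0.00939), microglia and macrophage markers (exact permutation p = 0.0127) and endothelial markers (exact permutation p = 0.00204). After adjustment over the 40 lists, the smallest of these was 0.0816, so 0 list means passed.

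The mean of 6 lists (astrocyte, oligodendrocyte, microglia, endothelial, pericyte and fibroblast markers) differed by 0.214 log2 units in F1 METH (two-sided exact permutation p = 0.0286, the smallest possible) and by -0.119 in F2 METH mice (exact permutation p = 0.143). In F2 the SD of this mean was 0.168 in saline and 0.0394 in METH libraries, so the F2 difference was smaller than the saline SD. As a source of the F1 difference in this mean, cortical tissue in the dissection is argued against. The slope on the cortical marker mean within groups predicted -1.93% of that difference, and -16.9% to 12.0% with each library left out. Of 2450 arrangements, 5 gave a difference between generations as large as 0.332 (highest other 0.347), but the lists were picked for this pattern, so chance is not excluded. A lower share of neuronal RNA in F1 METH mice stays open, since the test on spiny projection neuron genes did not decide (exact permutation p = 0.571). The estimate went the other way, with a list mean 0.106 log2 units higher in F1 METH, 23 members higher and 4 lower. An effect of the founder's treatment also stays open, and the pericyte list did not share the pattern, with 12 of 13 members higher in F1 and 10 of 13 higher in F2.

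Heat shock genes were lower in F2 METH mice, and high levels in F2 saline replicates 2 and 3 are a candidate source. Without them the list was called lower at the preset correlation (adjusted p = 0.0132, 33 of 39 members lower), but other splits of the F2 libraries called a median of 13 of 40 lists at that setting, so this call does not decide. The median moved from -0.30 to -0.11. With an estimated correlation, camera's unadjusted p was 0.0499 with all F2 libraries and 0.443 without these 2. After adjustment over the lists it passed in neither fit (adjusted p = 0.475 and 0.691). F2 saline replicates 2 and 3 stay open as the source of part or all of the pattern, as do chance and an effect of the founder's treatment.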

How the results depend on the processing

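Alternatives with a robust dispersion, a cortical covariate or doubted libraries left out, and lists for the difference, were chosen after seeing the data. For genes called, F1, edgeR's 0 became 7 with DESeq2, 3 with limma-voom with or without quality weights, and 1 in the fit of all 15 libraries. It became 1 by limma-trend on TPM + 1, TPM + 0.1 or FPKM + 1, 1 without libraries with Slc17a7 above 100 CPM, 774 at an unadjusted p under 0.05 and 110 with a 2-fold change added. The Slc17a7 limit left only F1 saline replicates 2 and 4 and F1 METH replicates 1 and 2. For genes called, F2, 0 became 9 with DESeq2, 1 with limma-voom in both forms, 1 by the Slc17a7 limit and 4 without F2 saline replicates 2 and 3. Unadjusted it became 863, and 63 with a 2-fold change. For genes called, difference between generations, 1 became 0 with a mean CPM of at least 1, which removes Aox4, and with limma-voom in both forms or the Slc17a7 limit, 4 with DESeq2 and 943 at an unadjusted p under 0.05. Besides the replicate block, the other alternatives run kept these counts; except for the filter and looser thresholds, the cause was not tested.

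Leaving out each library gave 0 to 2 genes in F1 (1 without F1 saline replicate 1 or F1 METH replicate 1, 2 without F1 saline replicate 2), 0 to 1 in F2 (1 without F2 saline replicate 1, 3 or 4 or F2 METH replicate 1) and 0 to 2 for the difference (2 without F1 saline replicate 2, 0 otherwise). The lists called, 18, 16 and 19, became 0 with an estimated correlation (in F2 also without F2 saline replicates 2 and 3) and 0 with fry, and 15 to 22, 10 to 19 (10 without F2 METH replicate 1) and 16 to 21 with each library left out. The correlation of fold changes, F1 with F2, was -0.00493 with a mean CPM of at least 1 and -0.0145 to 0.0696 with each library left out. Calls shared between generations were 19 with the same direction at an unadjusted p under 0.05. They stayed at 0 with each library left out. That was fixed beforehand, since the other generation kept its full fit with 0 calls, so it shows no stability. Of 857 recomputed fold changes of named genes, 829 kept their side of the threshold and direction where p was under 0.05. Besides these, 12 newly passed, 16 no longer passed, those of Aox4, and 0 reversed. Sign changes with p at or above 0.05 numbered 35. Only the Aox4 difference passed in the main fits, so keeping the same side says little about stability.

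Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0345 to 0.401 in F1 and -0.0618 to 0.0388 in F2, and 1 of 3 and 0 of 4 METH libraries correlated best with their own number. With the replicate block, 0, 0 and 0 genes and 23, 17 and 23 lists were called in F1, F2 and for the difference. In simulations, 11.9% of 1.5-fold changes were called in F1 and 41.8% in F2, which limits what was detectable. The simulated genes were independent, whereas another split of the real F1 libraries called 270 genes. Detection in the real libraries may therefore be lower and false calls more frequent than simulated.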

Other observations

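The tests of lists for the difference were chosen after the data were seen. Genes whose groups did not overlap numbered 1017 of 18499 in F1, 5.50% where chance gives 5.71%, and 460 of 18093 in F2, 2.54% where chance gives 2.86%.

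With a real count of 0 genes called by edgeR, each of the 35 splits in F1 (highest other 270) and in F2 (highest other 25) reaches it, so these counts say nothing about chance. For the following counts chance could not be excluded. Of 35 splits of the F1 libraries, the real one included, 15 gave at least 774 genes at an unadjusted p under 0.05 (highest other 2861). In the same splits, 20 called at least 7 genes with DESeq2 (highest other 998) and 9 at least 18 lists (highest other 26). Of 35 splits of the F2 libraries, 15 gave at least 863 unadjusted (highest other 2486). There, 19 called at least 9 genes with DESeq2 (highest other 479) and 11 at least 16 lists (highest other 23). For the difference, 100 of 2450 splits were drawn: 18 called at least 1 gene (highest other 299), 47 gave at least 943 unadjusted (highest other 2584) and 15 at least 19 lists (highest other 27). Splits with many more genes than the real one point to a structure of the samples. The F1 split with 270 genes set apart saline replicate 4 and METH replicates 1 and 2, the 3 F1 libraries with the lowest Slc17a7. The F1 split with 192 genes set apart saline replicates 1 and 3 and METH replicate 3, the 3 with the highest Slc17a7. The F2 split with 25 genes set apart saline replicate 4 and METH replicates 2, 3 and 4. Their Slc17a7 was 67.8 to 183 CPM, and at most 57.0 CPM in the other F2 libraries.

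ICR mice are outbred, and haplotypes that differ between animals may place genes with small p close together. Among the 200 genes with the smallest p, 35 non-overlapping pairs lay within 1 Mb in F1 and 42 in F2. In 1000 random sets the median was 30 and the 95th percentile 43 for F1, and 31 and 43 for F2, so the test did not decide. Of 35 splits, 28 in F1 (highest other 128) and 20 in F2 (highest other 142) gave as many pairs, so chance could not be excluded. The median over the other splits was 48 pairs in F1 and 45 in F2, above the 95th percentile of the random sets. Genes with small p thus often lay close together when these libraries were grouped without regard to the founder's treatment. The source of this closeness was not tested.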
